A study of Homo sapiens with 6 samples.

How the data were processed

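The study mapped m6A in U2OS cells treated with a control siRNA or with 1 of 2 siRNAs against YTHDF2 (DF2). Per the labels' protocols, cytoplasmic RNA was fragmented to about 100 nt and immunoprecipitated with an anti-m6A antibody, and input RNA was sequenced beside it. The 6 samples are 1 input and 1 m6A-IP for each of 3 conditions, grouped by the treatment in the labels. The submitters' processing notes name HISAT2 and the hg38 genome build, with no version of HISAT2. The peak caller, the way replicates were merged and the gene annotation release are not given in the sources used here.

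The authors deposited 1 peak list per condition, each marked as merged over r1 and r2, although the labels hold 1 input and 1 m6A-IP sample per condition. A list gives the blocks of each peak, its strand, its gene and the transcript parts it touches, per the file headers. The deposited score of a peak is a whole number of 3 or more whose definition is not given in the sources used here. Its median differed between lists, at 158 in control, 33 with siRNA 1 and 99 with siRNA 2, so scores were ranked only within a list. Where the percentile or rank of a peak is given for more than 1 list, the values stand side by side as a description and measure no change. The fold enrichment (ratio) of each peak is the authors' value, per the file headers. The −log10 FDR of each peak is also the authors' value per the file headers, and every deposited peak had an FDR under 0.05. The covered width was a multiple of 200 bases in 86.7% of control peaks, 92.7% of siRNA 1 peaks and 90.4% of siRNA 2 peaks. Read counts and library depths were not used here, so the depth behind a peak is unknown, and the precision given is that of the number of peaks.

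Blocks were read with start positions raised by 1. On the minus strand the block sizes run in the opposite order to the block starts, and they were reversed, after which all block ends matched the peak ends. Peaks of 2 lists counted as shared with at least 1 base of a block in common on the same strand. Peaks that overlap between lists were joined into regions, with no joining of peaks within a list alone, and each region was classed by the lists it held. A gene was lost if it had a peak in control and in neither siRNA list, and gained if it had a peak in both siRNA lists and not in control. Because 1 control list enters both comparisons, each count was set beside the same count for the other ways of setting 1 list against the rest. The planned number of genes that independent lists would share is not given, since the number of genes that could hold a peak is not known from the lists. Shares have 95% exact binomial (Clopper-Pearson) intervals. No p-value was computed across peaks or genes.

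The region of a peak was taken from the authors' annotation, since the position of its midpoint in a transcript needs gene models not used here. A peak that includes a stop codon was called a stop codon peak, otherwise a peak with 5′ UTR and no 3′ UTR a 5′ UTR peak, with 3′ UTR and no 5′ UTR a 3′ UTR peak, and with coding sequence alone a coding peak. DRACH motifs and random placement of peaks on exons were planned and were not analysed here, as they need a genome sequence and exons.

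The RefSeq gene table of assembly GRCh38.p14 was used for names, biotypes and gene spans. Of 10785 symbols in the lists, 8843 were current, 658 were updated through a single older synonym and 1284 were kept as in the files. Of control peaks with a matched symbol, 96.8% lay within 2000 bases of that gene in RefSeq, with 97.9% for siRNA 1 and 97.3% for siRNA 2.

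Before the data were examined, 26 gene lists, the comparisons and the alternatives were fixed. The share of lost and of gained members of each list, among members with a peak in any list, was given as a percentile among 10000 random lists of the same size matched on RefSeq gene span decile and biotype. Exonic length, the planned match, was not used here, and the score and number of a gene's peaks were not matched. Percentiles describe these lists and are not tests. Named genes were chosen by a rule fixed with the lists. It took up to 10 members per class of the m6A writer, reader and eraser, and reported YTHDF2 target lists, the 10 control peaks with the highest score, the 12 lost genes with the highest control score, the 12 gained genes with the highest mean score percentile, and up to 4 members of each other list. Where a list had 5 or fewer lost or gained members, they were named, those outside the rule after their values were seen, apart from some lost receptor and kinase genes that are not reported here. The overlap code was tested on simulated data, with 5950 of 5950 planted regions given their planted class. A simulated list of 40 genes with 10 lost, where 10% of all genes were lost, came at percentile 99.4, and 8 of 100 unchanged simulated lists lay above percentile 95.

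Alternatives for the overlaps were at least 50% of each peak in common, gaps of up to 100 bases, strand ignored, the top 50% of each list by score, the same number of top peaks (13147) from each list, and merging overlapping peaks within a list. Genes were also compared with 1 siRNA at a time and with protein-coding genes alone. Peaks with an FDR under 0.01 and the top 50% by fold enrichment were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.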

Results

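N6-methyladenosine (m6A), an internal modification of messenger RNA, was mapped in U2OS cells, a human bone osteosarcoma line. Cytoplasmic RNA was broken into fragments of about 100 nt and enriched with an anti-m6A antibody (m6A-IP), with unenriched input RNA beside it. Cells had received a control siRNA, DF2 siRNA 1 or DF2 siRNA 2, the latter both directed at YTHDF2 (DF2), a reader protein that binds m6A and promotes decay of the bound RNA. The 6 libraries were 1 m6A-IP and 1 input for each of the 3 conditions, and the processed data were 1 merged peak list per condition. The control list held 15272 peaks in 9618 genes and covered 12.1 Mb. The siRNA 1 list held 13147 peaks in 8417 genes and covered 9.12 Mb, and the siRNA 2 list held 13310 peaks in 8609 genes and covered 10.1 Mb. The median peak covered 600 bases in each list. With 1 list per condition there were no replicates to compare, so no value has an SD and no difference was tested against replicate error. Intervals are 95% exact binomial intervals and cover counting error only. Read depths behind the peaks were not used here, and no list measures the level of an RNA.

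YTHDF2 itself carried 1 m6A peak in each list, on the plus strand of chromosome 1 (hg38). In the control list the peak ran from 28740371 to 28769316 and covered 2000 bases of 5′ UTR, coding sequence, stop codon and 3′ UTR. In both siRNA lists it ran from 28742575 to 28769116, covered 1600 bases and no longer included the 5′ UTR. By the authors' score, the YTHDF2 peak stood at percentile 99.1 of the control list, 84.3 of the siRNA 1 list and 66.6 of the siRNA 2 list. The authors' fold enrichment of the peak was 91.0 in the control list, 57.2 in the siRNA 1 list and 53.1 in the siRNA 2 list. Scores and folds are the authors' values and describe a peak within its own list, so these figures measure no change in methylation. The lists cannot show how far either siRNA lowered YTHDF2 RNA.

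**Figure D1:**
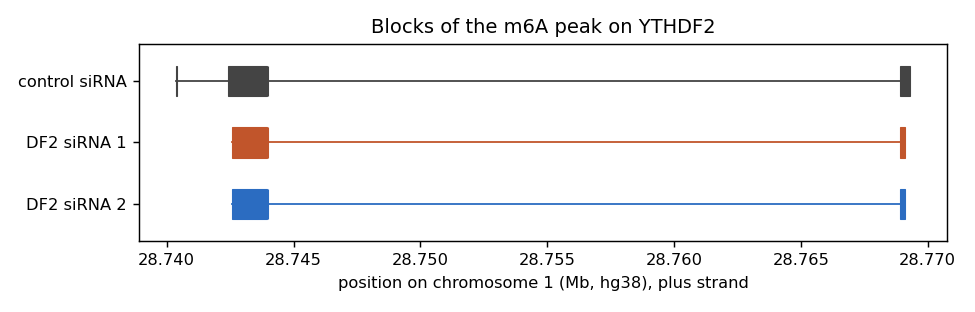
Blocks of the YTHDF2 m6A peak in each of the 3 lists, by position on chromosome 1 (Mb, hg38), where boxes are covered bases and thin lines join the blocks of 1 peak. The control peak starts at 28740371 and both siRNA peaks start at 28742575.

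The strongest m6A peaks of U2OS cells were present with and without DF2 siRNA. The 10 genes with the highest control scores were SLC7A5, an amino acid transporter, DAG1 (dystroglycan), PRSS23, CTSZ (cathepsin Z), the non-coding RNA MALAT1, BASP1, CD59, GPRC5A, HSPA8 (a constitutive chaperone) and LTBR. All 10 control peaks overlapped a peak of both siRNA lists, and 8 of them included a stop codon. The SLC7A5 peak, in the 3′ UTR on the minus strand of chromosome 16 (87830368 to 87831567 in the control list), had the highest score in every list, with a fold of 141 in control, 656 with siRNA 1 and 226 with siRNA 2. The MALAT1 peak covered the same 800 bases of chromosome 11, from 65499962 to 65500761, in all 3 lists. Of the top 10% of control peaks by score, 97.6% (96.7 to 98.3) lay in all 3 lists, against 62.8% (62.1 to 63.6) of all control peaks. The corresponding shares of the top 10% were 95.4% (94.1 to 96.4) for siRNA 1 and 98.9% (98.2 to 99.4) for siRNA 2.

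Whether DF2 siRNA moved the whole set of peaks was asked by comparing each pair of lists, with at least 1 base in common on the same strand counted as shared. Of control peaks, 67.1% (66.4 to 67.9) were found in the siRNA 1 list and 73.4% (72.7 to 74.1) in the siRNA 2 list. The DF2 siRNA lists, which are both shorter, had a larger share of their peaks in another list. Of siRNA 1 peaks, 83.6% (83.0 to 84.2) were found with siRNA 2 and 81.5% (80.8 to 82.1) in control. Of siRNA 2 peaks, 80.5% (79.9 to 81.2) were found with siRNA 1 and 86.1% (85.5 to 86.7) in control. In the top 50% by score that order turned, with 98.7% of siRNA 2 peaks found with siRNA 1 and 93.2% in control, and by fold enrichment the shares were 98.6% and 98.4%. The order was kept with an FDR under 0.01 (87.0% with siRNA 1 and 91.7% in control). It was also kept with the same number of top peaks (81.5% and 83.5%) and with at least 50% of each peak in common (74.6% and 76.0%). Joining peaks that overlap between lists gave 17771 regions, of which 9021 held a peak in all 3 lists.

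**Figure D2:**
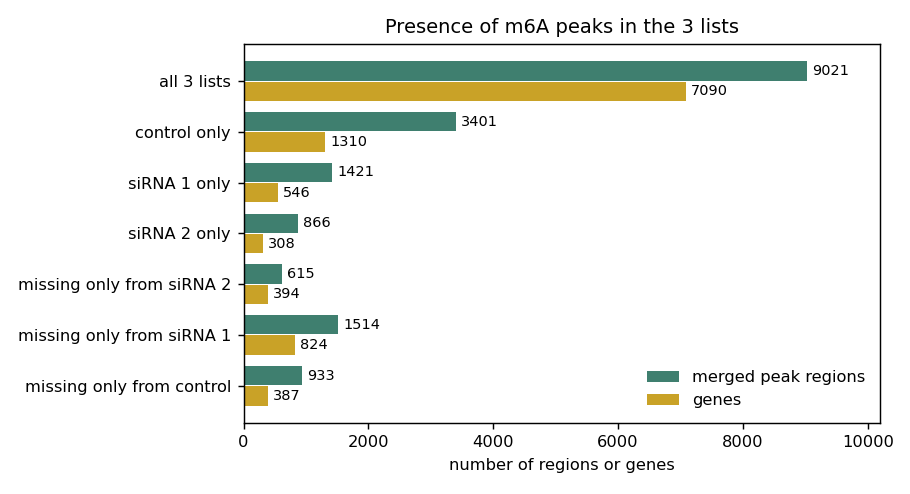
Number of merged peak regions and of genes (horizontal axis) by the lists in which they hold an m6A peak (vertical axis), over 17771 regions and 10859 genes. The classes of control alone (3401 regions, 1310 genes) and missing only from control (933 regions, 387 genes) stand beside the same classes for each siRNA.

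Genes that held m6A peaks in control cells and none with either DF2 siRNA numbered 1310. There were 754 with the same number of top peaks from each list, 751 with an FDR under 0.01, and 179 and 101 in the top 50% by score and by fold enrichment. The 12 with the highest control score were CD164, a sialomucin, PERP, a desmosome-associated p53 target, SLC25A3, the mitochondrial phosphate carrier, TMPO, a lamina-associated protein, ERGIC2, SLC71A1 (HIAT1 in the files), SEC31A, a COPII coat subunit, ELOVL5, a fatty acid elongase, ARPC2, an Arp2/3 subunit, EMC4, HMGN3 and RAB1A. In 10 of the 12 the control peak included the stop codon. The CD164 peak covered 600 bases between 109368556 and 109370548 on the minus strand of chromosome 6, with a score of 1508 and a fold of 15.5. The TMPO peak, at 98547587 to 98548386 on chromosome 12, had the highest fold of the 12, 42.4, and a −log10 FDR of 9.80. In 7 of the 12 the −log10 FDR was 2 or less, and the lowest was 1.43.

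The 1310 lost genes compare with 546 genes found only with siRNA 1 and 308 found only with siRNA 2, the other ways of setting 1 list against the rest. Against control alone, siRNA 1 lacked peaks in 2134 genes and siRNA 2 in 1704. Both comparisons use the same control list, so the number of genes they share is not read as a shared effect. At the level of peaks, 3401 control peaks overlapped none in either siRNA list, against 1421 for siRNA 1 and 866 for siRNA 2. The median score percentile of these 3401 peaks was 15.4 within the control list, against 66.6 for control peaks found in all 3 lists, and 48.4% (46.7 to 50.1) had an FDR of 0.01 or more, against 18.8% of all control peaks. With the same number of top peaks from each list, control-only peaks fell to 1842 against 1495 and 1069, and in the top 50% of each list by score they fell to 384 against 371 and 38. Among peaks with an FDR under 0.01 the counts fell to 1755 against 653 and 356, and the ratio of control to siRNA 1 was 2.69, against 2.39 over all peaks.

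Genes with m6A peaks under both DF2 siRNAs and none in control numbered 387. There were 191 with an FDR under 0.01, and 151 and 22 in the top 50% by score and by fold enrichment. The 12 with the highest mean score percentile were FTH1 (ferritin heavy chain), PKM (pyruvate kinase), TMSB4X (thymosin beta 4), CLPTM1L, L1CAM, a neural adhesion molecule, ECEL1, YBX3, a cold-shock-domain protein, PFN1 (profilin), AL021546.6, HN1, CNPY2 and RP11-977G19.10. The FTH1 peak covered 400 bases of 5′ UTR, coding sequence and stop codon between 61967116 and 61967660 on the minus strand of chromosome 11, at percentile 99.9 with siRNA 1 and 99.7 with siRNA 2. The PKM peak lay in the 3′ UTR on chromosome 15, from 72199029 to 72199599 with siRNA 1 and to 72199399 with siRNA 2. The YBX3 and PFN1 peaks lay in or next to the 5′ UTR in both siRNA lists. For 6 of the 12 genes the siRNA 2 peak had a −log10 FDR of 2 or less. The RP11-977G19.10 and CNPY2 peaks overlap in place, and the peak given to AL021546.6 overlaps a control peak assigned to another gene.

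The 387 gained genes compare with 824 missing only from the siRNA 1 list and 394 missing only from the siRNA 2 list, so absence from control alone was not the most frequent pattern. With siRNA 1 alone 933 genes were gained and with siRNA 2 alone 695. Among merged regions, 933 were missing only from control, 1514 only from siRNA 1 and 615 only from siRNA 2. In the top 50% of each list by score 301 regions were missing only from control, 41 only from siRNA 1 and 132 only from siRNA 2, so the order of the 3 lists changed. By fold enrichment these counts were 53, 45 and 14. The order was kept with an FDR under 0.01 (436, 823 and 219) and with the same number of top peaks (1044, 1183 and 556). It was also kept with at least 50% of each peak in common (1511, 1728 and 637).

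Most m6A peaks lay at stop codons and in 3′ UTRs in all 3 conditions. Peaks whose annotation by the authors included the stop codon made up 42.9% (42.2 to 43.7) of the control list, 43.5% (42.7 to 44.4) with siRNA 1 and 43.7% (42.8 to 44.5) with siRNA 2. Peaks of the 5′ UTR made up 14.4% in control, 18.9% (18.2 to 19.5) with siRNA 1 and 16.6% (15.9 to 17.2) with siRNA 2. Counting only peaks that touch no other part of a coding transcript, the 5′ UTR shares were 7.22%, 7.85% and 7.84%, so the lists then differed little. Peaks of non-coding RNA made up 12.6% (12.1 to 13.1) in control, 7.61% (7.16 to 8.07) with siRNA 1 and 10.6% (10.1 to 11.2) with siRNA 2.

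The 5′ UTR share was highest among peaks of the DF2 siRNA lists that control cells lacked. Of siRNA 1 peaks shared with siRNA 2 and not control, 399 of 1013 or 39.4% (36.4 to 42.5) were 5′ UTR peaks, and of the matching siRNA 2 peaks 413 of 982 or 42.1% (38.9 to 45.2). With at least 50% of each peak in common asked for, the siRNA 1 share was 25.9%. Among peaks in all 3 lists the share was 13.4% (12.7 to 14.1) of control peaks and 12.9% (12.3 to 13.6) of siRNA 1 peaks. HIF1A, MAP2K1, LOX and HSPB8 were among the genes with such 5′ peaks under both siRNAs and no control peak. The share was lower among control peaks missing only from siRNA 1, at 15.6% (13.8 to 17.4), and among those missing only from siRNA 2, at 19.8% (16.9 to 23.1), the latter still above that of control peaks in all 3 lists. Peaks found with siRNA 1 alone had 46.2%, with siRNA 2 alone 29.8%, and in control alone 15.7%. Peaks found in control alone held fewer stop codons (23.1%, 21.6 to 24.5) than control peaks in all 3 lists (53.5%, 52.5 to 54.5) and more 3′ UTR peaks (27.7%) and non-coding RNA peaks (21.1%). The low stop codon share was not particular to control, at 21.5% with siRNA 1 alone and 15.5% with siRNA 2 alone. Non-coding RNA peaks made up 5.98% with siRNA 1 alone and 20.7% with siRNA 2 alone, and 3′ UTR peaks 14.7% and 17.3%. If 5′ UTR is given only to peaks that touch no other part of a coding transcript, the share of siRNA 1 peaks shared with siRNA 2 and not control is 19.3%, against 4.39% of siRNA 1 peaks in all 3 lists. By the same count the share was 10.8% of peaks in control alone and 10.7% of control peaks missing from either siRNA list alone, also above the 5.15% of control peaks in all 3 lists.

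**Figure D3:**
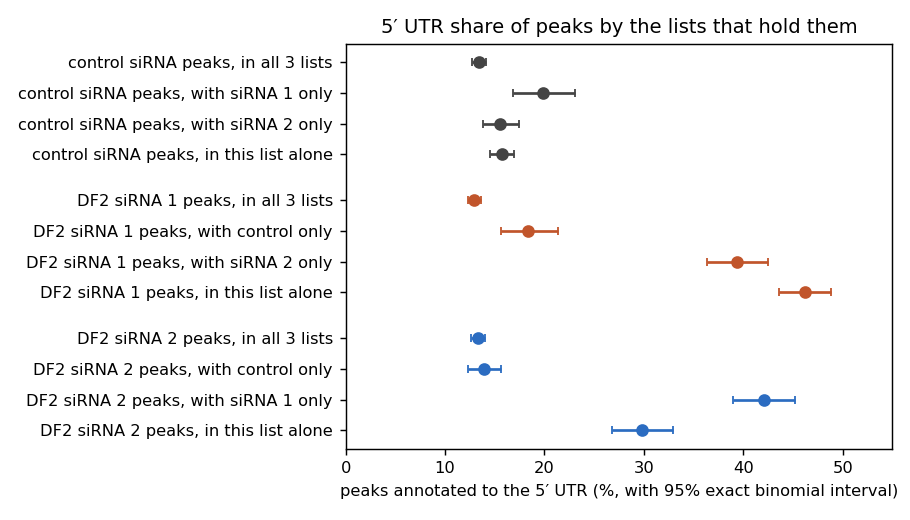
Share of peaks annotated to the 5′ UTR (horizontal axis, percent, with 95% exact binomial intervals as bars) for each list, split by which other lists hold an overlapping peak (vertical axis). Peaks of the siRNA lists that lack a control peak lie between 29.8% and 46.2%, and those in all 3 lists near 13%.

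The m6A machinery and the transcripts reported to be bound by YTHDF2 had peaks with and without DF2 siRNA. Of 12 genes of the m6A writer complex, which deposits the mark, and related methyltransferases, 10 had a peak in each of the 3 lists. These were CBLL1, METTL14, METTL16, METTL3, PCIF1, RBM15, RBM15B, VIRMA, WTAP and ZC3H13, and in 9 of them the strongest control peak overlapped both siRNA lists. METTL3, the catalytic subunit, was the exception, with its control peak at 21503864 to 21504063 on chromosome 14, the stronger of its 2 siRNA 1 peaks at 21503264 to 21503463 and its siRNA 2 peak at 21510833 to 21511375. Of 21 readers and erasers, 15 had a control peak, 15 a siRNA 1 peak and 13 a siRNA 2 peak. The erasers FTO and ALKBH5 and the readers YTHDF1, IGF2BP2, IGF2BP3 and PRRC2A were among 8 of 10 named members whose strongest control peak overlapped both siRNA lists. The exceptions were YTHDC1, whose control peak overlapped neither, and IGF2BP1, whose control peak overlapped siRNA 2 alone. RBMX had no siRNA 2 peak, FXR1 had no siRNA 1 peak, and HNRNPA2B1 and HNRNPC had a peak with siRNA 1 alone. FMR1 was the only member lost, with a control score of 8. Of 24 reported YTHDF2 targets, 18 had a control peak, 19 a siRNA 1 peak and 18 a siRNA 2 peak, with 0 lost and 0 gained. In all 10 targets with a peak in every list that were taken in alphabetical order, MYC, EGFR, CREBBP and AXIN1 among them, the strongest control peak overlapped both siRNA lists. The MYC peak, at the stop codon on chromosome 8, stood at percentile 99.7, 98.8 and 99.1.

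Immediate-early, chromatin and signalling genes lost few members. Of 38 immediate-early genes, which respond first to growth signals and stress, 34 had a peak in each list and 0 were lost, including IER2, CCN1, MYC and MCL1 (percentile 3.76 of lost members among 10000 matched random lists). Of 58 chromatin regulators, 49 had a control peak, 51 a siRNA 1 peak and 49 a siRNA 2 peak, and 0 were lost (percentile 0.215), among them EP300, ARID1A, KMT2D and NSD1. Of 54 genes of TGF-beta, WNT, NOTCH and Hippo signalling, 49, 46 and 47 had a peak in control, siRNA 1 and siRNA 2, with TGFBR1, NOTCH2 and CTNNB1 in all 3 and SMAD4 lost (percentile 2.49). Of 35 heat-shock and unfolded-protein genes 25, 28 and 24 had a peak, with 0 lost (percentile 4.49) and HSPB8 gained. Interferon genes (21, 20 and 20 of 38) had 0 lost and 0 gained. Of the 9223 protein-coding genes and lncRNAs matched in RefSeq that had a peak in any list, from which the random lists were drawn, 9.47% were lost and 3.75% gained. The random lists were not matched on the score or number of a gene's peaks. Peaks found in control alone had a median score percentile of 15.4, while those of IER2, CCN1, MYC and TGFBR1 stood at 99.7 to 99.9. KMT2D had 7 control peaks and NSD1 had 5. The low percentiles thus do not set these lists apart from other genes with strong or several peaks. With the same number of top peaks from each list, the immediate-early, signalling and heat-shock percentiles were 10.9, 8.03 and 10.1, no longer at the low end, while that of chromatin regulators was 0.995. For heat-shock genes it was 23.5 with siRNA 2 alone.

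Autophagy and glycolysis lists held more gained genes than most matched random lists. Of 34 autophagy and lysosome genes, 17 had a control peak, 20 a siRNA 1 peak and 19 a siRNA 2 peak. The 4 gained were ATG9A, GABARAPL1, MAP1LC3B, a ubiquitin-like protein of autophagosomes, and TFE3, a lysosomal transcription factor (percentile 99.1), and the lost ones were ATG12 and ATG16L1. The GABARAPL1 peaks lay at different places with each siRNA. Of 26 glycolysis genes 11, 12 and 13 had a peak, with PKM and HIF1A gained (percentile 95.1) and PFKFB2 lost. The glycolysis percentile fell below 95 in 3 of the 4 alternatives, with a lowest value of 92.3.

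Ribosomal protein and histone genes lay at the other end. Of 78 ribosomal protein genes, 19 had a control peak, 14 a siRNA 1 peak and 15 a siRNA 2 peak, and RPL10, RPL15, RPL37A and RPL7 were lost (percentile 95.9), all with control scores of 23 or less. With the same number of top peaks from each list, 1 ribosomal protein gene was lost, at percentile 61.1. Of 58 replication histone genes 12, 8 and 8 had a peak, and H2BC11, H3C8 and H4C4 were lost (percentile 95.3, and 92.3 against random lists not matched on gene span). Nuclear-encoded OXPHOS genes (22, 25 and 19 of 77) lost ATP5MG, NDUFA6, NDUFB3, SDHC and UQCRC1 and gained NDUFA11, NDUFB7 and NDUFS7. The NDUFS7 peaks lay at different places with each siRNA. Across the 26 lists fixed beforehand, 48 percentiles of lost or gained members could be formed. Of these 4 were at 5 or under, all for lost members, and 4 at 95 or over. Evenly spread percentiles would put 5% at each end, but counts this small need not spread evenly. Lists with 0 gained members came no lower than percentile 7.8, so the low end was out of reach for gained members. Single lists at these ends carry little weight.

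The other lists lay between these ends. DNA repair genes (25, 20 and 20 of 36) lost MRE11, WRN and XRCC6, p53 targets (22, 21 and 20 of 27) lost FAS, RRM2B and TP53INP1, and cell cycle genes (24, 23 and 22 of 45) lost CENPE, E2F7, E2F8 and TTK and gained CCND3 and ESPL1. RNA decay factors (37, 38 and 31 of 52) lost CNOT10, CNOT11, CNOT7 and RC3H2 and gained SMG5, and stress granule genes (19, 21 and 18 of 29) lost CPEB1. Receptor and kinase genes (35, 36 and 33 of 48) had FGFR2 and NF1 among the lost genes and gained EPHB4 and MAP2K1. Matrix and osteoblast genes (18, 22 and 19 of 39) gained LOX. Cholesterol and lipid genes (20, 20 and 16 of 31) lost INSIG2 and LSS and gained MVD, and proteasome genes (11, 13 and 11 of 31) lost PSMA4, PSMD1 and PSMD14 and gained PSMD3 and PSMD4. Of the lost genes named here, CNOT10, CNOT7, CPEB1, MRE11, RRM2B, LSS, PSMA4 and PSMD14 had control scores of 8 or less. The lowest score of the control list was 3. Scores were 14 to 86 for INSIG2, FGFR2, TP53INP1 and E2F7, and 144 to 452 for XRCC6, WRN, TTK, NF1, FAS and CNOT11. Those of the other lost genes are not given here. Long non-coding RNAs of a list fixed as nuclear (12, 10 and 9 of 20) lost DANCR, at a control score of 7, while MALAT1 and NORAD had peaks in all 3 lists. The MALAT1 peak stood at percentile 99.4 or above in each list, although the RNA was cytoplasmic per the labels. How free that RNA was of nuclear RNA was not measured here. Markers of cells that a U2OS culture should lack were scarce, with 2 of 19 blood cell markers in each list, all of low score, and 0 of 20 markers of hepatocytes, neurons and keratinocytes. The lists hold peaks of chromosomes 1 to 22 and X, and 0 of 15 mitochondrially encoded genes were among them.

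**Figure D4:**
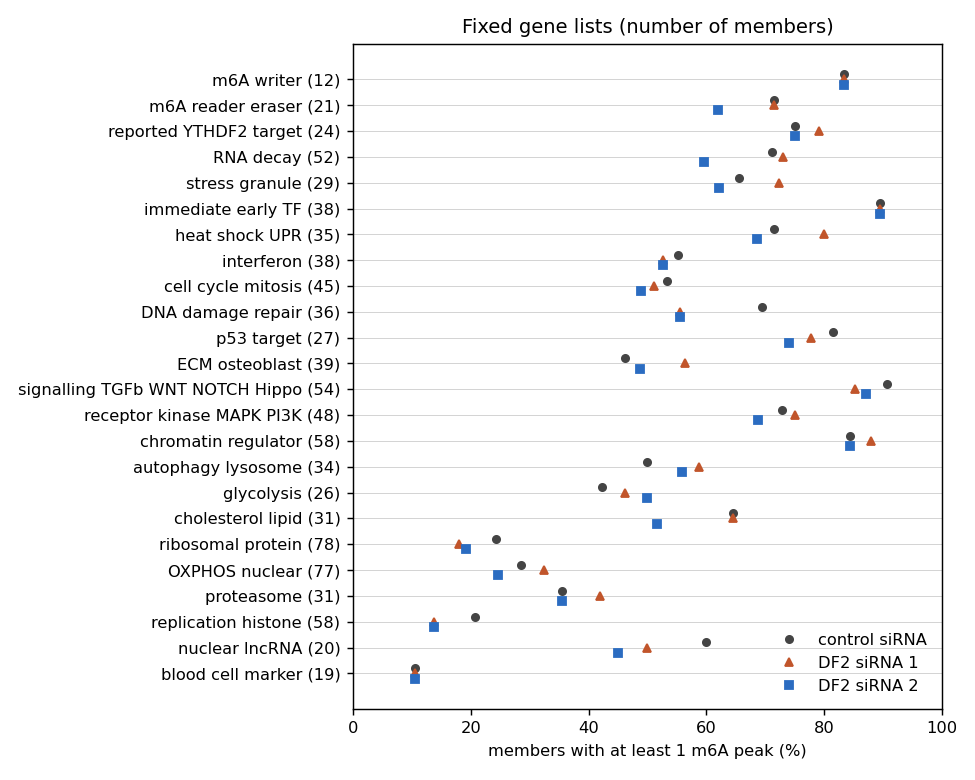
Percent of members of each fixed gene list with at least 1 m6A peak (horizontal axis) in the control, siRNA 1 and siRNA 2 lists, with the number of members in brackets. Gene lists whose members had a peak in no condition are left out, and each point is 1 merged peak list with no replicate.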

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

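In 5 gene lists the number of members with a peak moved in opposite directions with the 2 DF2 siRNAs, and none of these differences was tested, since each condition has 1 peak list. RNA decay factors went from 37 in control to 38 with siRNA 1 and 31 with siRNA 2, a difference of 7 members between the siRNAs. Nuclear OXPHOS genes went from 22 to 25 and 19, a difference of 6. Heat-shock and unfolded-protein genes went from 25 to 28 and 24, a difference of 4. Stress granule genes went from 19 to 21 and 18, and receptor and kinase genes from 35 to 36 and 33, a difference of 3 in each.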

How the results depend on the processing

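The alternatives with an FDR under 0.01 or the top 50% by fold enrichment were chosen after seeing the data. Gaps of up to 100 bases, ignored strand and merging within a list left the shares within their intervals and the counts within 1.5 times; the rest moved values as follows. With at least 50% of each peak in common, control peaks found with siRNA 1, control peaks found with siRNA 2 and siRNA 1 peaks found with siRNA 2 came to 57.7%, 66.2% and 75.6%, regions missing only from control to 1511 and the 5′ UTR share of siRNA 1 peaks shared with siRNA 2 and not control to 25.9%. In the top 50% by score the same 3 shares were 93.0%, 91.6% and 91.8%, control-only peaks 384, regions missing only from control 301, lost genes 179, gained genes 151, that 5′ UTR share 33.4% and the stop codon share of control peaks 62.1%. With the same number of top peaks, the control shares were 76.4% and 81.5%, control-only peaks 1842, lost genes 754 and the stop codon share 48.1%, while regions missing only from control rose to 1044 and gained genes to 475, as the control list is the one shortened most. With an FDR under 0.01 the 3 shares were 75.4%, 82.3% and 90.6%, control-only peaks 1755, regions missing only from control 436, lost genes 751, gained genes 191 and the stop codon share 47.8%. In the top 50% by fold enrichment the 3 shares were 92.5%, 95.3% and 97.6%, control-only peaks 207, regions missing only from control 53, lost genes 101, gained genes 22 and the stop codon share 59.5%. The settings by score, FDR and fold enrichment count part of each list against all peaks of the others, which lowers the counts by construction. Against siRNA 1 alone 2134 genes were lost and 933 gained, and with siRNA 2 alone 695 were gained, since 1 list is asked for and not both. Among protein-coding genes 790 were lost, as fewer genes enter. Giving 5′ UTR only to peaks with no coding sequence, stop codon or 3′ UTR put the 5′ UTR share at 19.3%, by its construction. Of 142 other values under an alternative, 70 were counted as moved, 22 up and 48 down, with causes not tested. Shares and counts had the same bounds, while a gene list percentile counted as moved once it left the low or high end. DRACH motifs, shuffled peaks, the midpoint region and the exonic length match were not run, and depth could not be weighed without read counts. No paired analysis was possible because each condition has 1 list merged over r1 and r2, so no replicate numbers remain to pair.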

Other observations

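The tests weighed below were set before their results were seen, with some exceptions chosen after. These were the chromosome shares of peaks outside the 5′ UTR and of peaks in 1 list alone, and the control peaks elsewhere in the same gene. The FDR limit of 0.01, the fold enrichment ranks and the gene classes were likewise chosen after. The long non-coding RNAs and p53 targets named here were also picked after their values were seen. Lost and gained genes differed in kind, but a lost gene needs a peak in 1 list and a gained gene in 2. Genes found with 1 siRNA alone, the class most like lost genes, were not sorted by kind. The difference is therefore not read as an effect of DF2 siRNA. Of 1292 lost genes with a symbol, 60.8% (58.0 to 63.4) were protein-coding in RefSeq, 6.81% were lncRNAs and 26.5% had a symbol without a match there. Of 382 gained genes, 88.0% (84.3 to 91.0) were protein-coding, close to the 88.5% of genes with a peak in all 3 lists. Among long non-coding RNAs, NEAT1 and HOTAIR had peaks in control and with siRNA 1 and none with siRNA 2, while NORAD, PVT1, TUG1 and SNHG16 had peaks in all 3. Among p53 targets, CDKN1A, the cyclin-dependent kinase inhibitor p21, had a peak with siRNA 1 alone, at percentile 91.8 of that list. CCND3, HIF1A and MAP2K1 gained peaks that lie in or next to the 5′ UTR.

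Peaks found with both DF2 siRNAs and not in control were rich in 5′ UTR peaks, at 39.4% of siRNA 1 peaks, or 25.9% with at least 50% of each peak in common. In the top 50% of the siRNA 1 list by score the 5′ UTR share fell to 33.4% (28.6 to 38.6). Under this count of 5′ UTR peaks, weak siRNA 1 peaks as the whole source are thus argued against. Counting only peaks that touch no other part of a coding transcript, the share was 19.3% before any cut by score. The bounds set for the test do not suit that count, and its top 50% by score was not examined. The reading therefore holds for the first count alone. Weak signal in control is not weighed by this test, as a list of called peaks cannot show places just under the calling limit. Of the matching siRNA 2 peaks, 43.1% had an FDR of 0.01 or more, against 17.3% of all siRNA 2 peaks. Shifted peak borders as the main source are also argued against, since 6.27% (4.10 to 9.11) of the 399 gained 5′ UTR peaks lay within 200 genomic bases of a control peak; that distance misses neighbours across an intron, and 66.9% (62.1 to 71.5) lay in genes with a control peak elsewhere, against 57.8% (53.8 to 61.8) of other gained peaks, but 11.5% (8.57 to 15.1) in genes with a control peak that includes 5′ UTR and 18.5% (14.9 to 22.7) in genes with one of 5′ UTR or coding sequence and no 3′ UTR. A GC bias between libraries cannot be told apart from this pattern, since the intervals overlap: 22.1% (18.1 to 26.4) of the gained 5′ UTR peaks lay on the GC-rich chromosomes 16, 17, 19 and 22, against 19.3% (17.2 to 21.6) in all 3 lists, while other gained siRNA 1 peaks reached 34.0% (30.3 to 37.9) against 23.8% (22.9 to 24.7). A change in 5′ UTR methylation with less YTHDF2 stays open and untested, and the 46.2% 5′ UTR share of peaks with siRNA 1 alone shows that the pattern is not limited to peaks that both siRNAs share.

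The control list held more peaks of its own than either siRNA list. Both technical explanations may account for much of this: with the same number of top peaks the control-only count was 1.23 times (1.15 to 1.32) the larger siRNA count, and in the top 50% by score 5.03% (4.55 to 5.55) of control peaks were private against 5.65% (5.11 to 6.24) with siRNA 1 and 0.569% with siRNA 2. The same-number setting drops the lowest scores as well, so list length and low score are not separated by it. With all peaks the ratio was 2.39, with an FDR under 0.01 it rose to 2.69, and in the top 50% by fold enrichment it was 1.80, so part of the excess is not accounted for. On chromosomes 16, 17, 19 and 22 lay 16.5% (15.2 to 17.8) of control-only peaks, against 23.6% (22.7 to 24.4) of control peaks in all 3 lists. Peaks with siRNA 1 alone reached 27.3% and with siRNA 2 alone 23.8%. A GC bias between libraries was not tested for this excess. A loss of m6A peaks with DF2 siRNA was not shown by these lists and stays untested.

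The YTHDF2 peak ranked lower in both siRNA lists. Among 7048 genes with a peak in all 3 lists it stood at rank 128 by score in control, 1721 with siRNA 1 and 3504 with siRNA 2. Ranks within separate lists measure no change, and a general reordering between lists cannot be told apart from something particular to YTHDF2. By score, 1.49% of these genes (105) stood at least 1593 places lower in each siRNA list, between the bounds set for either reading. That is the smaller YTHDF2 shift, seen with siRNA 1. Genes that also match its 3376 places with siRNA 2 were not counted. By fold enrichment, where the smaller YTHDF2 shift was 1116 places, the share was 15.7%. Less YTHDF2 RNA in siRNA-treated cells, which could lower a score that follows RNA abundance, is a candidate explanation that needs RNA levels not analysed here.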
